A study of Saccharolobus islandicus with 6 samples.

How the data were processed

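RNA of 6 libraries of Saccharolobus islandicus REY15A was sequenced, 3 from cells with the empty expression plasmid and 3 from cells with the plasmid carrying aCcr1. Per the series' design text and the labels, cultures were started at an optical density (600 nm) of 0.05, induced with arabinose and harvested after 12 h at about 0.2, RNA was extracted with Trizol, and sequencing was on an Illumina NovaSeq. Per the series' design text, clean reads were aligned to the REY15A genome and summarised by the authors as FPKM per gene. The submitters' processing notes name HISAT2 version 2.0.5. The read counter and the annotation version are not given in the sources used here. The labels' extraction text also speaks of retinas and their build field names a mouse genome. Both are at odds with the organism and with the coordinates in the table, so neither was used, and the library kit named in the same text was not taken as known. The authors' own comparison used DEGSeq with an adjusted p of 0.05 and no minimum fold, per the series' design text, and its results were not used here.

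The deposited FPKM values of 2781 genes were read with the gene positions, lengths and product descriptions of the same table. Samples were grouped by their titles, and the columns of the aCcr1 libraries were matched to them by their names, which carry 0197 in place of aCcr1. FPKM multiplied by gene length was a whole multiple of 1 read (tolerance 0.001) for 16683 of 16686 values, 99.98%. The 3 exceptions belong to SIRE_RS00995 in the aCcr1 libraries. The reads so recovered numbered 5359666 to 7096648 per library, with a median of 542 reads per gene, and the authors' scale was 0.960 to 1.04 times that total. The 10 genes with most reads took 23.8% to 25.7% of them. Depth limits the weakly expressed genes: 1 read per kilobase was worth 0.141 to 0.185 FPKM. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 6.66 to 149.7). 0 identifiers matched the reference gene table, which is of another strain, so names come from the deposited table alone. The gene locus tags of the REY15A genome project do not occur in the table, so the genes fixed by such tags were sought by description, and the cell division genes were identified by the words CdvA, Snf7 and Vps4.

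FPKM values were tested as log2(FPKM + 1), for the 2628 genes with a mean FPKM of at least 1 over the 6 libraries, with limma 3.58.1 in R 4.3.3 (trend in the prior variance, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are aCcr1 over empty vector. The median log2 fold change was -0.015, and -0.064 after rescaling without the 10 genes of highest mean FPKM. Gene lists were fixed before the data were examined as 28 sets of words matched on the descriptions, and 27 had at least 3 tested members. They were tested with camera (preset inter-gene correlation 0.01) and, as alternatives, with an estimated correlation and with fry. Counts adjusted over the list alone apply the Benjamini-Hochberg method to the members' p-values. Because word matches caught unrelated genes, a second version without 131 such memberships was made from the product names after the data were seen. Genes named in the text were chosen by a rule fixed beforehand: the aCcr1 gene, the cell division genes, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean FPKM of at least 10, no overlap between groups and no transposase, and up to 4 members of each list with the smallest adjusted p. Outside this rule, SIRE_RS05935, SIRE_RS00300, SIRE_RS07075, SIRE_RS07070, SIRE_RS09180, SIRE_RS00990, SIRE_RS01000 and the ends of gene runs were chosen after their values were seen. A single gene was compared with an exact permutation test, whose smallest two-sided p with 3 against 3 is 0.1. The exchange of libraries within same-numbered pairs was added after the data were seen.

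The same replicate numbers occur in both groups. The deviations of same-numbered libraries from their group means correlated at 0.471, 0.250 and 0.115 for numbers 1, 2 and 3, all above 0.1. The numbers were therefore treated as pairing the libraries in an alternative fit with replicate number as a block. The main fit did not use the pairing, and p-values and counts come from it unless another setting is named. The pairing is uncertain, since empty-vector replicate 2 correlated more with aCcr1 replicate 3 (0.350) than with replicate 2, and empty-vector replicate 3 correlated with aCcr1 replicate 2 at 0.0854. The pairing comes from the data, since the labels do not say what a number marks. The fit was repeated with pseudocounts of 0.1 and 10, no filter and a mean FPKM of at least 10, median-of-ratios scaling, quantile normalization, rescaling without the 10 highest genes, limma without the trend, with robust moderation and with array weights, replicate number as a block, voom on the recovered reads, the table without transposases, and leaving out each library. Fits without both libraries numbered 1 and with each library's trend on gene length removed were added after the data were seen. The fit was tested on simulated reads of 2628 genes for empty vector against aCcr1, with 200 genes changed. It recovered 76.1% of genes changed by 0.5 on the log2 scale, 92.5% at 1 and 100% at 2, and called 3 of 2428 unchanged genes. The simulated genes were independent, had no replicate structure and shared a dispersion of 0.00537, a median over the empty-vector libraries. Chi-square per degree of freedom reached 149.7 between real aCcr1 replicates and 39.15 between empty-vector replicates, so these rates need not hold for the real libraries. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.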

Results

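Cells of Saccharolobus islandicus REY15A, a thermoacidophilic archaeon, were compared by RNA sequencing of 6 libraries. 3 libraries came from cells with the empty plasmid pSeSD and 3 from cells with the same plasmid carrying the gene of aCcr1, a ribbon-helix-helix DNA-binding protein. All were induced with arabinose and harvested after 12 h, at an optical density of about 0.2. The table held FPKM values of 2781 genes. The reads recovered from these values numbered 5690203, 7019819 and 6050943 in empty-vector replicates 1, 2 and 3, and 5359666, 6748462 and 7096648 in aCcr1 replicates 1, 2 and 3. The first principal component carried 66.6% of the variance and separated the groups. The second carried 17.7%, and replicate 1 of each group lay apart from the other libraries on it. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

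The comparison addressed which genes change when aCcr1 is overexpressed, in a study of its part in the cell cycle. A ribbon-helix-helix gene of the CopG family, SIRE_RS00995 (positions 174622 to 174798, plus strand, of the REY15A chromosome), stood at 3251 ± 10.7 FPKM (SD, n = 3) with the aCcr1 plasmid and at 538 ± 53.7 (SD, n = 3) with the empty plasmid. Its values were 3262, 3252 and 3241 FPKM in the aCcr1 libraries and 581, 478 and 555 in the empty-vector libraries. The limma log2 fold change was 2.60 ± 0.10 (SE, adjusted p = 2.77e-06), and the exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow (exact p = 0.25, also the smallest possible, with exchange only within same-numbered pairs). The table did not pair any gene with the name aCcr1, so this gene was taken as the overexpressed one only after its values were seen. Of the 7 ribbon-helix-helix genes of this kind, the next largest log2 fold change was 0.91. The 3 aCcr1 values of SIRE_RS00995 were the only 3 of 16686 in the table that did not come out as whole reads within 0.001, and they varied by 0.328% (coefficient of variation), below each of the other 250 genes at 1000 to 10000 FPKM, whose median was 11.0%. The size of the rise rests on these 3 values, and how they were made is not known.

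**Figure D1:**
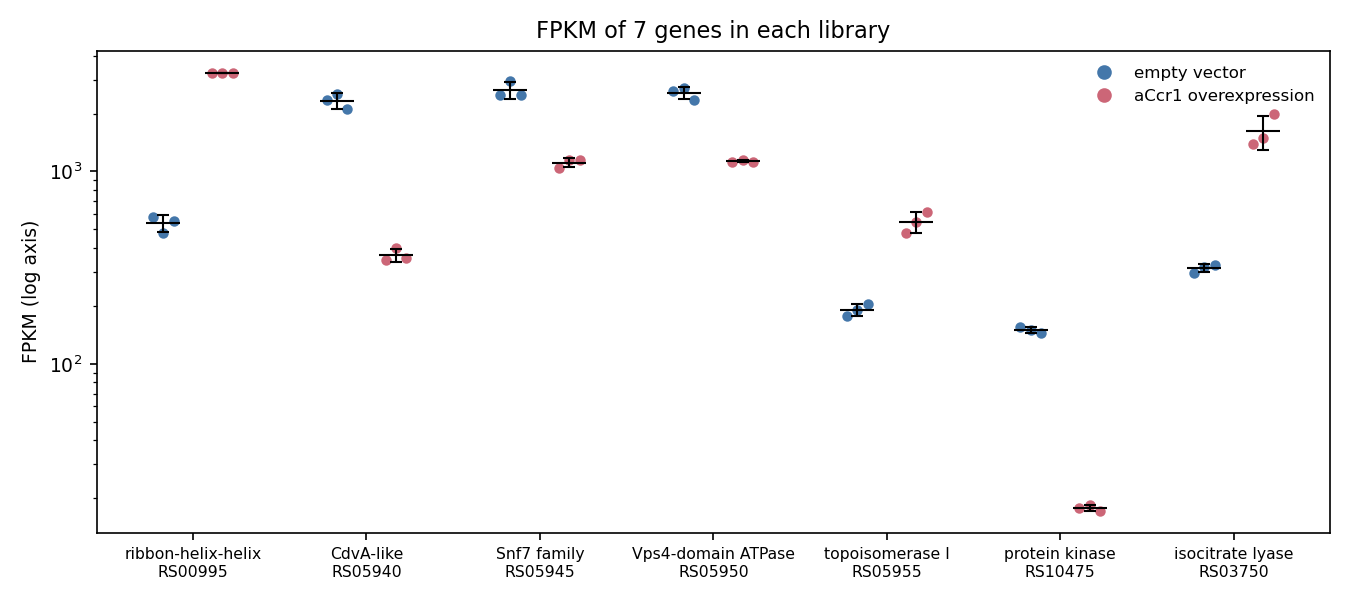
FPKM on a log axis of 7 genes in the 3 empty-vector and 3 aCcr1 libraries; points are libraries, bars the mean and SD. The CdvA-like gene stood at 2331 FPKM with the empty plasmid and at 367 with the aCcr1 plasmid, and the groups did not overlap in any of the 7 genes.

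The 3 genes of the Cdv cluster, of the archaeal division machinery, fell in the aCcr1 libraries, and the genes of isocitrate lyase, rubrerythrin and peroxiredoxin rose. The oxidative stress and metal list as a whole held 14 genes that rose and 8 that fell. Of 2628 genes tested with limma, 1113 passed an adjusted p of 0.05, of which 565 rose and 548 fell. After rescaling without the 10 genes of highest mean FPKM 493 rose and 617 fell, so the balance of rises and falls depends on the scaling. The change was at least 2-fold for 204 of them, with 77 up and 127 down. The product name of 58 of the 204 was hypothetical protein, though a description could hold further words, as that of SIRE_RS03185 did. Among all 2781 genes in the table, 649 had this product name or none. All 3 libraries of one group lay beyond all 3 of the other for 1411 genes, or 53.7%, where chance gives 10% if all 6 libraries can be exchanged. Only same-numbered libraries can be exchanged if the numbers pair them, and the 3 other splits that part all pairs gave 54 to 81 such genes. A gene whose groups are apart in the real split cannot be apart in another split, so these counts are no measure of chance. The fold changes are on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. With a pseudocount of 10 in place of 1, the 2-fold count was 129.

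**Figure D2:**
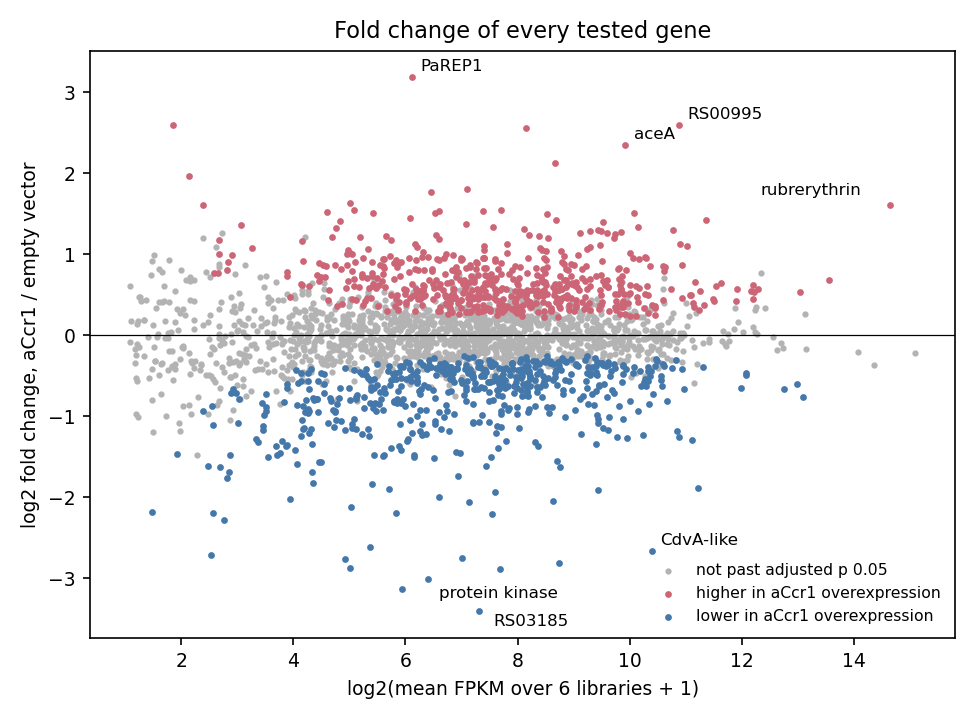
Log2 fold change of each of 2628 tested genes against its mean level over the 6 libraries, on a log2 scale; colours mark the 565 genes that rose and the 548 that fell past adjusted p 0.05. The CdvA-like gene lies at -2.66 and isocitrate lyase at 2.35.

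Among genes with a mean FPKM of at least 10, the largest rise with a pseudocount of 1 was that of SIRE_RS14695, a PaREP1 family gene, from 12.9 ± 3.98 to 125 ± 34.0 FPKM (SD, n = 3 per group), a log2 fold change of 3.19 ± 0.26 (SE, limma adjusted p = 9.71e-05). With a pseudocount of 10 its log2 fold change was 2.54, no longer the largest. PaREP1 genes form a family, and reads of near-identical copies cannot be assigned with certainty. A B12-binding radical SAM protein, SIRE_RS07740, rose 5.91-fold, from 81.1 to 484 FPKM. Isocitrate lyase, aceA (SIRE_RS03750), an enzyme of the glyoxylate shunt, rose 5.09-fold from 314 ± 14.3 to 1623 ± 327 FPKM, and homoserine kinase (SIRE_RS00830), of threonine synthesis, rose 4.39-fold to 662 ± 37.6. A winged helix-turn-helix regulator, SIRE_RS00635, and its neighbour SIRE_RS00640 rose 3.49-fold and 3.42-fold. Rubrerythrin (SIRE_RS12945), a non-haem iron protein that removes peroxide, rose 3.05-fold from an already high 12619 ± 388 to 38733 ± 5129 FPKM. The remaining members of the 10 largest rises were SIRE_RS12840, a hypothetical protein at 3.11-fold, and acetyl-CoA C-acetyltransferase (SIRE_RS01475) at 2.93-fold. SIRE_RS07740, SIRE_RS12840 and SIRE_RS01475 overlap a gene on the opposite strand, and the counting is not stated to use strand.

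Among the same genes the largest fall was that of SIRE_RS03185, a hypothetical protein at positions 602622 to 603386, from 289 ± 23.6 to 26.5 ± 3.15 FPKM (SD, n = 3 per group; log2 fold change -3.40 ± 0.12, SE; limma adjusted p = 1.99e-06). Its neighbour SIRE_RS03180, which overlaps a gene on the opposite strand, fell 8.79-fold. A protein kinase, SIRE_RS10475, fell 8.03-fold from 150 ± 5.84 to 17.8 ± 0.572 FPKM, and an ATP/GTP-binding protein, SIRE_RS00425, fell 7.04-fold from 749 ± 63.8 to 106 ± 18.5. The adjacent genes SIRE_RS00090 and SIRE_RS00085 fell 7.36-fold and 6.70-fold, and a thermopsin family protease, SIRE_RS03515, fell 4.62-fold. The hypothetical genes SIRE_RS03415 and SIRE_RS10690, at 56.3 ± 30.7 and 52.0 ± 8.26 FPKM with the empty plasmid, fell 7.30-fold and 6.77-fold. With a pseudocount of 10 the log2 fold changes of SIRE_RS03180, SIRE_RS03415 and SIRE_RS10690 were -2.46, -1.93 and -1.87, against -3.14, -2.87 and -2.76 with a pseudocount of 1. The 10 largest rises, the 10 largest falls and the genes of the Cdv cluster, 22 genes in all, stayed on the same side of the threshold in all 462 refits under 21 alternative settings. Most were picked as the most extreme in these same libraries, so this is no independent support.

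The 3 genes of the Cdv cluster, which code for the archaeal division machinery related to ESCRT-III, fell together. The CdvA-like gene SIRE_RS05940 (positions 1126025 to 1126741, plus strand) fell 6.33-fold, from 2331 ± 219 to 367 ± 29.0 FPKM (SD, n = 3 per group; log2 fold change -2.66 ± 0.10, SE; limma adjusted p = 2.78e-06). The next gene, the Snf7 family gene SIRE_RS05945, the family of ESCRT-III proteins, fell 2.38-fold from 2647 ± 263 to 1110 ± 57.8 FPKM. The gene after it, SIRE_RS05950, whose product carries a Vps4 domain, fell 2.26-fold from 2557 ± 187 to 1128 ± 12.8 FPKM. Upstream of them, SIRE_RS05935 on the minus strand fell too, by 1.34 on the log2 scale. On the other side, beginning 26 bp after SIRE_RS05950 and on the opposite strand, DNA topoisomerase I (SIRE_RS05955) rose 2.84-fold from 191 ± 13.1 to 545 ± 67.7 FPKM, and RNA polymerase subunit K (SIRE_RS05960) rose 2.52-fold. The fixed cell division list had 5 tested members, of which 1 rose, 3 fell and 1 did not pass. Its other members, a pair of CDC48 family ATPases, were matched only by a domain name, and one of them, SIRE_RS09320, rose 1.38-fold, a call that was lost when any single library other than aCcr1 replicate 1 was left out (adjusted p 0.0570 to 0.109). The list's camera adjusted p was 0.279 with both of them and 0.00950 without them, a choice made after the data were seen. It was 0.00950 to 0.630 over the 22 alternatives that kept camera's preset correlation. Without the CDC48 genes the list is the 3 neighbouring genes of the cluster. The preset correlation of 0.01 treats these as nearly independent, so the value of 0.00950 may be too small. For all 5 members camera with an estimated correlation gave an adjusted p = 0.984, and fry gave an adjusted p of 0.00352. The other ESCRT-III genes of this strain were not identified in the table and are not reported here.

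**Figure D3:**
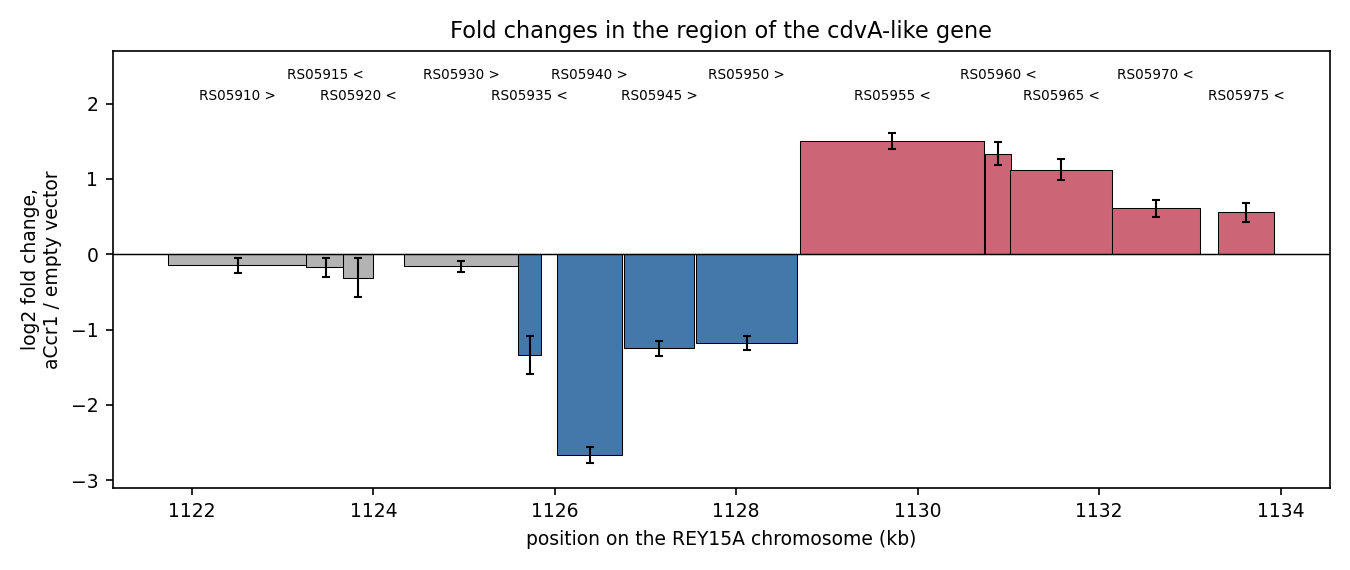
Log2 fold change (aCcr1 over empty vector) of each gene along the REY15A chromosome around the CdvA-like gene; bar width is gene length, whiskers are SE, arrowheads give the strand, and grey bars did not pass adjusted p 0.05. The change turns from a fall of 2.26-fold at SIRE_RS05950 to a rise of 2.84-fold at SIRE_RS05955.

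Genes that copy DNA moved both ways. In the list of replication initiation and replisome genes, 6 of 22 rose, 7 fell and 9 did not pass. DNA polymerase I (SIRE_RS07370), the replicative family B enzyme in this lineage, rose 2.86-fold from 561 ± 26.0 to 1611 ± 181 FPKM (SD, n = 3 per group). A Cdc6-type AAA ATPase, SIRE_RS08850, an initiator of replication, fell 1.93-fold from 383 ± 32.0 to 198 ± 15.5 FPKM, and the MCM helicase gene SIRE_RS06220 fell 1.58-fold. Of 5 topoisomerase genes 1 rose and 2 fell (5 further members of that list were proteins of other kinds caught by its words), the latter being both subunits of topoisomerase VI (SIRE_RS05660, 1.65-fold, and SIRE_RS05655, 1.47-fold, named topoisomerase IV subunit A in the table). Of the chromosome segregation list 6 of 14 rose and 2 fell. Its ParA family members, ATPases of partitioning systems, split, with SIRE_RS00660 up 2.89-fold and SIRE_RS01335 down 1.96-fold. In the chromatin list 1 of 6 rose and 1 fell, the former being AcuC of the histone deacetylase family (SIRE_RS10035) and the latter the chromatin protein Cren7 (SIRE_RS05625), 1.89-fold lower. The gene of Alba (SIRE_RS05695) stood at 23803 ± 2842 and 18514 ± 1653 FPKM and did not pass (limma adjusted p = 0.0714; 0.0244 with replicate number as a block, and 0.00854 to 0.204 over 21 alternatives). In DNA repair 4 of 21 rose and 6 fell. NurA nuclease genes made up 4 of the 6, with SIRE_RS00465 2.31-fold lower, while another NurA gene, SIRE_RS00300, rose by 0.34 on the log2 scale. SIRE_RS00300 lay in a run of 5 genes that all rose (1.41-fold at the median), with an SMC family ATPase and exonuclease SbcCD subunit D. The NurA gene SIRE_RS00065 lay in a run of 6 genes that all fell (1.92-fold at the median).

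Of the CRISPR-Cas genes more rose than fell, and of the nucleotide synthesis genes more fell than rose, but neither list passed the camera test. In the CRISPR-Cas list 18 of 32 rose and 4 fell, and the counts adjusted over the list alone were also 18 and 4. Many of the 18 lay in runs of neighbouring genes that rose together, SIRE_RS04485 to SIRE_RS04510 (6 genes) and SIRE_RS03050 to SIRE_RS03080 (7 genes, the last named hypothetical protein). Camera's preset correlation of 0.01 treats such neighbours as nearly independent. The type III-B genes cmr4 (SIRE_RS04485) and cmr1 (SIRE_RS04495) rose 1.90-fold and 1.78-fold, and csa5 of the type I-A system (SIRE_RS03875) rose 1.60-fold, while the CRISPR-associated gene SIRE_RS07845 fell 2.86-fold. In nucleotide synthesis 4 of 34 rose, 14 fell and 16 did not pass, or 4 and 15 adjusted over the list alone. A purine gene run fell, with phosphoribosylaminoimidazolesuccinocarboxamide synthase (SIRE_RS07020) 2.41-fold and purS (SIRE_RS07015) 2.24-fold lower, while the GMP synthase genes SIRE_RS01200 and SIRE_RS03265 rose 1.67-fold and 1.62-fold. In the list of TCA cycle and central carbon 23 of 52 rose and 7 fell, the same counts as adjusted over the list alone. Beside isocitrate lyase, pyruvate ferredoxin oxidoreductase (SIRE_RS12060) rose 1.80-fold, citrate synthase (SIRE_RS13220) 1.67-fold and phosphoglycerate kinase (SIRE_RS07395) 1.56-fold. 19 of the 52 were enzymes of other pathways caught by the words of the list, and without them, a choice made after the data were seen, 11 of 33 rose and 6 fell. The camera adjusted p of the list was 0.356 without them, against 0.0564 with all 52. Of 67 ribosomal protein genes 1 rose and 11 fell, or 1 and 9 adjusted over the list alone, with L44e (SIRE_RS05300) 1.54-fold lower. The camera adjusted p was 0.0564 for each of the CRISPR-Cas, nucleotide and central carbon lists and 0.117 for ribosomal proteins. With replicate number as a block it was 0.0479, 0.0135, 0.0190 and 0.0305. Over the 22 alternatives that kept camera's preset correlation it lay between 0.0214 and 0.117 for CRISPR-Cas and 0.0135 and 0.122 for nucleotide synthesis. It lay between 0.0190 and 0.356 for central carbon and 0.0230 and 0.543 for ribosomal proteins. With an estimated correlation all 4 had an adjusted p = 0.984, and fry gave adjusted p-values of 0.00719, 0.0566, 0.00866 and 0.255 in that order. 0 of 27 lists passed (4 without empty-vector replicate 1 or aCcr1 replicate 3, 3 without aCcr1 replicate 2, 1 without empty-vector replicate 2 or aCcr1 replicate 1), 4 had an unadjusted camera p under 0.05, and fry, which asks only whether a list's genes move one way on balance, called 8.

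**Figure D4:**
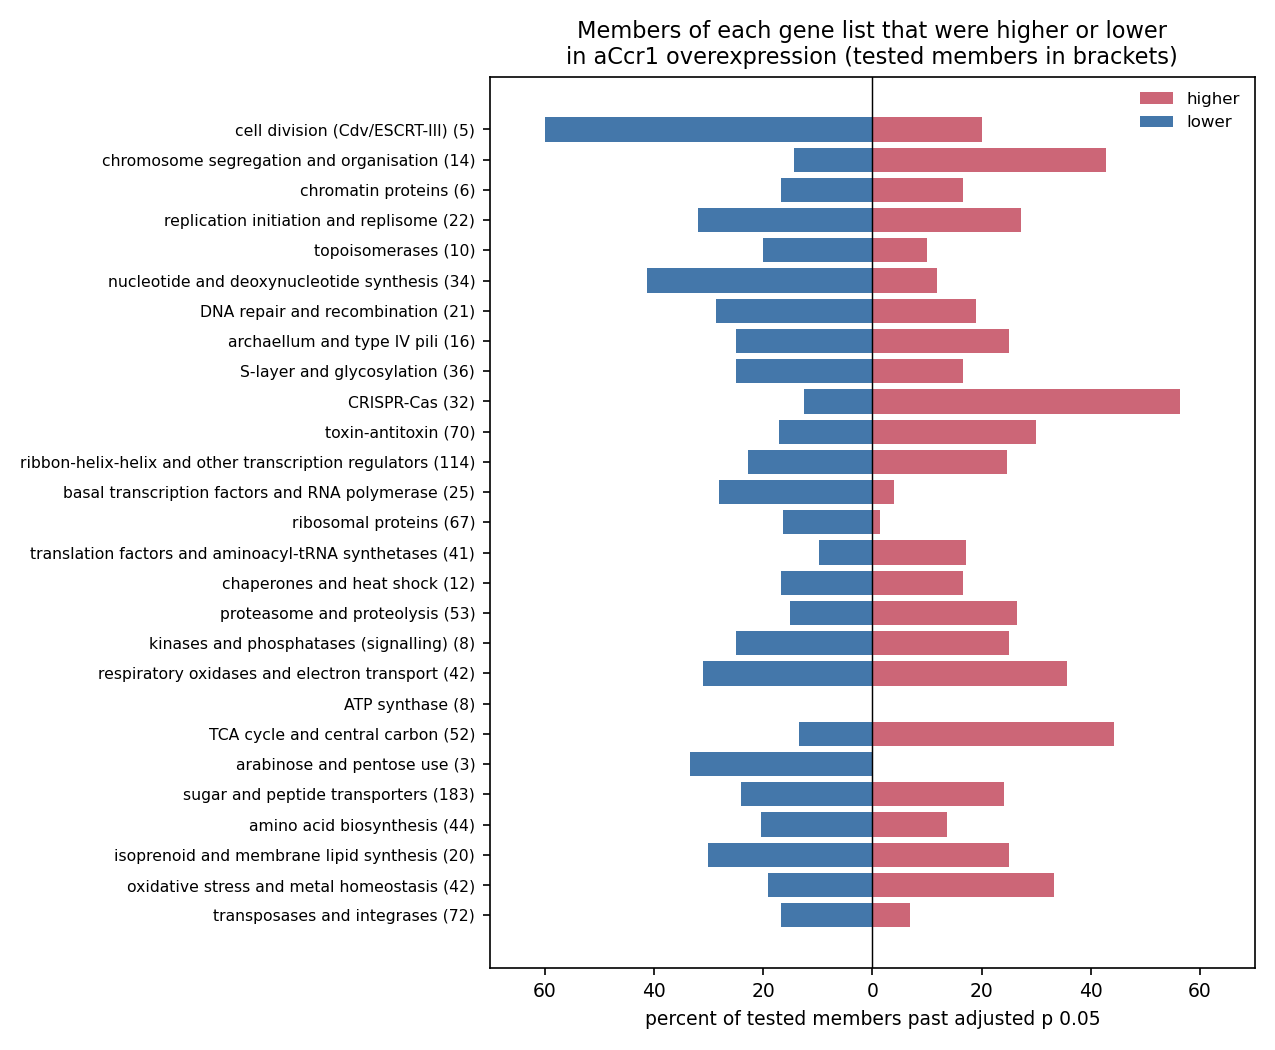
Percent of the tested members of each of 27 gene lists that rose (right) or fell (left) past adjusted p 0.05 in the aCcr1 libraries. Of 32 CRISPR-Cas genes 18 rose, and of 34 nucleotide synthesis genes 14 fell.

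Other groups held changes in both directions. In oxidative stress and metal homeostasis 14 of 42 rose and 8 fell, with peroxiredoxin (SIRE_RS01755) up 2.69-fold from 1424 ± 9.46 to 3841 ± 315 FPKM (SD, n = 3 per group). An iron-containing redox enzyme gene of the list, SIRE_RS12635, fell 2.32-fold. SIRE_RS03185, the hypothetical protein with the largest fall (10.6-fold), was matched to this list by its description. The list's camera adjusted p was 0.320. Of 8 protein kinase and phosphatase genes 2 rose and 2 fell, and beside SIRE_RS10475 the kinase SIRE_RS10350 fell 2.10-fold. Of 42 respiratory genes 15 rose and 13 fell, with the cytochrome b gene SIRE_RS11515 and the oxidase subunit gene SIRE_RS11520 each 1.62-fold higher and a Rieske protein (SIRE_RS01995) 2.19-fold lower. None of 8 ATP synthase genes passed limma's test, but V-type subunit F (SIRE_RS07330) did with replicate number as a block (adjusted p = 0.00281, against 0.0855 without it, and 0.00281 to 0.231 over 21 alternatives). V-type subunit I (SIRE_RS07335) stood at 1036 ± 31.0 and 948 ± 91.1 FPKM. Of 183 transporter genes 44 rose and 44 fell, among them a sugar ABC transporter (SIRE_RS05515, 3.09-fold lower) and a cytosine permease (SIRE_RS02840, 2.44-fold higher). In the list of archaellum and type IV pili 4 of 16 rose and 4 fell, with a flagellar hook-basal body protein gene (SIRE_RS09985) down by 1.44 on the log2 scale. 5 of its members, SIRE_RS00425 among them, are general ATPases matched only by the words type IV in the name of a toxin-antitoxin domain.

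In the list of transcription regulators 28 of 114 rose and 26 fell, but 32 of the 114 were other proteins caught by its words, and of the remaining 82 genes 16 rose and 23 fell. Of 25 genes of RNA polymerase and basal factors 1 rose and 7 fell, with the transcription factor B family genes SIRE_RS08730 and SIRE_RS05790 2.32-fold and 1.64-fold lower. Of 70 toxin-antitoxin genes 21 rose and 12 fell, with an AbrB family gene (SIRE_RS09950) 2.39-fold lower. In the chaperone list 2 of 12 rose and 2 fell. The 2 that fell were among 5 assembly chaperones of single enzymes or of the proteasome, and of the other 7 genes 2 rose and 0 fell by limma. Those that rose were the small heat shock genes SIRE_RS13135 (1.82-fold) and SIRE_RS01090 (1.81-fold). Of 53 protease and proteasome genes 14 rose and 8 fell. Of 41 translation factor and tRNA synthetase genes 7 rose and 4 fell, of 44 amino acid synthesis genes 6 rose and 9 fell, of 36 S-layer and glycosylation genes 6 rose and 9 fell, and of 20 isoprenoid lipid genes 5 rose and 6 fell. No gene matched the list of DNA damage induced pili and DNA import. As planned checks of the culture and the vector, 1 of 3 genes of pentose use, all matched by a xylose isomerase-like domain, fell and 0 rose. Both groups had arabinose and the plasmid, so neither these genes nor the marker genes named next can check the culture or the vector. Of the genes of the kind used as plasmid markers, orotate phosphoribosyltransferase (SIRE_RS07075) fell from 271 ± 62.9 to 125 ± 28.8 FPKM (SD, n = 3 per group), orotidine phosphate decarboxylase SIRE_RS07070 fell from 8.19 ± 0.667 to 4.68 ± 1.27, and the second such gene, SIRE_RS09180, did not pass (limma adjusted p = 0.731). Of 72 transposase and integrase genes 5 rose and 12 fell, and their near-identical copies leave each of these calls uncertain. Adjusted over the list alone, the members that rose and fell numbered 25 and 12 for toxin-antitoxin genes, 28 and 29 for regulators, 1 and 6 for RNA polymerase and basal factors, 5 and 3 for translation, 14 and 9 for proteases, 5 and 9 for S-layer and glycosylation, 6 and 7 for amino acid synthesis, 6 and 6 for isoprenoid lipids, 17 and 13 for respiration, 46 and 45 for transporters, 4 and 15 for nucleotide synthesis and 1 and 9 for ribosomal proteins, and did not differ for the other lists. The median, the mean and the camera direction differed in sign for the lists of chromatin, DNA repair, archaellum, regulators, translation, chaperones, kinases, pentose use, amino acid synthesis and isoprenoid lipids, none of which passed limma's camera. Without members caught by accident, a choice made after the data were seen, the genes that rose and fell numbered 4 and 2 of 9 for chromosome segregation, 4 and 13 of 32 for nucleotide synthesis, 2 and 2 of 11 for archaellum and pili, 14 and 9 of 54 for toxin-antitoxin, 10 and 5 of 27 for oxidative stress and metals, 7 and 3 of 38 for translation, 6 and 8 of 34 for S-layer and glycosylation, 1 and 10 of 65 for ribosomal proteins, 44 and 41 of 177 for transporters, 6 and 7 of 40 for amino acid synthesis and 4 and 5 of 15 for isoprenoid lipids.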

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

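Of the settings compared here, the fits without both libraries numbered 1, with the length trend removed and without list members matched by accident were chosen after the data were seen. The count of 1113 genes stayed within 1.5 times in all 21 refits: 1669 with array weights, the highest and just under that limit, 1505 with replicate number as a block, 1144 with voom, 1443 without both libraries numbered 1, and 871 to 1207 when single libraries were left out. All 1113 genes passed with the block too. Their direction could not differ, since in this balanced design the block leaves every fold change as it was. The count of 204 genes at 2-fold or more fell to 129 with a pseudocount of 10, which shrinks the fold change of weakly expressed genes, and lay between 195 and 230 without single libraries. SIRE_RS00995 kept its call throughout, with log2 fold changes of 2.52 to 2.66. The count of lists past camera was the least stable. In the main fit 3 lists lay at an adjusted p of 0.0564, and ribosomal proteins (0.117) and cell division (0.279) also passed in some settings. The main count was 0. It was 4 with replicate number as a block, quantile normalization or without both libraries numbered 1. With no filter, rescaling without the 10 highest genes, array weights or voom it was 3. With a mean FPKM of at least 10 or the length trend removed it was 2, and without members matched by accident 1. Leaving out single libraries gave 0 to 4 (4 without empty-vector replicate 1 or aCcr1 replicate 3, 3 without aCcr1 replicate 2, 1 without empty-vector replicate 2 or aCcr1 replicate 1). Fry, which tests another hypothesis, called 8. An estimated correlation called 0. For the other changes the cause was not tested. Among 2388 refits of named genes 2355 kept their call, 10 lost it, 22 gained it and 1 changed sign: the ATP synthase gene SIRE_RS07300, which did not pass, went from 0.14 to -0.0338 without aCcr1 replicate 1 (-0.0338 to 0.2583 over single libraries left out). The call of CDC48 ATPase SIRE_RS09320 (0.46) was lost in 7 of its refits, with no filter, with rescaling without the 10 highest genes and without each library but aCcr1 replicate 1. The block moved the calls of 4 named genes past the threshold, Alba, SIRE_RS06870, the ATP synthase gene SIRE_RS07330 and SIRE_RS01350, and of the 4 lists given in the report, and changed no other call among the named genes and the lists. Weakly expressed genes are the ones that depth limits.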

Other observations

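Of the tests in this part, those on the values of SIRE_RS00995, on splits of the libraries and on runs of genes were chosen only after the result was seen, and the others were written down before their results were computed. Among genes next to each other on one strand, 33 runs of at least 4 genes all passed limma's threshold in the same direction, 19 up and 14 down, and held 161 genes; 1000 shuffles of gene order gave 2.39 runs on average and 8 at most. The run with the largest median change, SIRE_RS09560 to SIRE_RS09580 (positions 1734725 to 1740663), fell 3.56-fold at the median over 5 genes, and includes a secretion ATPase gene of the type II/IV kind. A sugar ABC transporter run, SIRE_RS05500 to SIRE_RS05515, fell by 1.32 on the log2 scale at the median over 4 genes. The rising run with the largest median was SIRE_RS00635 to SIRE_RS00650 (2.97-fold at the median over 4 genes). It opens with the winged helix-turn-helix gene and ends with a CopG ribbon-helix-helix gene, which rose by 0.91 on the log2 scale. Other runs that rose include SIRE_RS03625 to SIRE_RS03640, with 2 thiolase domain genes (2.42-fold at the median over 4 genes). SIRE_RS02840 to SIRE_RS02855, which opens with the cytosine permease gene, rose 2.38-fold over 4 genes, and SIRE_RS12960 to SIRE_RS12975, with xanthine dehydrogenase family genes, 2.33-fold over 4 genes. The longest run, SIRE_RS08470 to SIRE_RS08515, held 10 genes, most of them for subunits of NADH-quinone oxidoreductase, and fell 1.49-fold at the median. The 2 type III-B CRISPR modules each formed a run that rose, SIRE_RS04485 to SIRE_RS04510 by 1.67-fold at the median over 6 genes and SIRE_RS03050 to SIRE_RS03080 by 1.36-fold over 7 genes.

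Neighbouring genes changed together more often than shuffled orders give. Of 1611 adjacent same-strand pairs, 72.7% moved the same way, while 10000 shuffled gene orders gave at most 54.8% (permutation p = 0.0001, the smallest they can give). Reads that run past gene ends without regard to strand would tie opposite-strand neighbours as closely, but within 100 bp same-strand pairs moved together more often, by 17.25 percentage points (95% bootstrap interval 12.7 to 21.8); as opposite-strand pairs moved the same way in 55.8%, above most but not all shuffles (highest 56.4%, permutation p = 0.0004), such reads may still account for a part. Gene dosage by distance from replication origins would give a trend along the chromosome. The Spearman rho across genes with distance to the nearest of 3 Cdc6 genes was 0.0696 (circular-shift p = 0.566). Genes are not independent replicates, and the distances were to Cdc6 genes and not to mapped origins, so this value cannot decide on gene dosage. Shared transcripts of neighbouring genes are a candidate explanation, as a hypothesis, since the table holds no transcript boundaries.

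The 3 aCcr1 values of SIRE_RS00995 imply 3113.68, 3858.69 and 3906.49 reads, while its 3 empty-vector values and all other values in the table are whole. Another gene length behind these values was tested, and 0 of 19971 whole lengths from 30 to 20000 bp turned all 3 into whole reads within 0.01. That reads of the plasmid copy were added in a separate step could not be tested, since the table has 1 row for this gene, and how these values were made stays open. Their coefficient of variation was 0.328%, against 9.98% in the empty-vector libraries. Beside it, on the opposite strand, SIRE_RS00990 stood at 725 ± 25.4 and 1409 ± 22.5 FPKM and SIRE_RS01000, which overlaps its end, at 263 ± 6.88 and 474 ± 30.1 (SD, n = 3 per group), and both rose; their values are whole reads.

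For the 1113 genes past the threshold, a trend on gene length between libraries was tested as a cause, and 1155 genes passed with it removed. This argues against a length trend as the whole cause. A few genes taking most of the reads was tested too, and 1110 passed after rescaling without the 10 highest. That total says little, since rescaling shifts the genes of a library nearly alike and trades rises for falls. There were 565 rises and 548 falls before it, and 493 and 617 after it. Of the 1113 genes 1041 still passed, in the same direction. For those genes this argues against a few highly expressed genes as the whole cause. The real split of the 6 libraries was the only 1 of 10 that called any gene, 1113 in all and 204 at 2-fold or more, and the highest of the other splits was 0 for both counts, also among the 3 others that part all same-numbered libraries; 10 splits are too few for a share under 0.05. The other splits mix the plasmids, so any difference between the plasmids adds to the spread within their sets, and their 0 is no measure of chance. For lists past camera the real split gave 0, which all 10 splits reach whatever the data, so this count says nothing about chance. Apart from that count, the highest other was 8, from the split of empty-vector replicate 1 and aCcr1 replicates 1 and 2 against the rest. This split mixes the plasmids but leaves a part of their difference in the comparison, and whether its lists reflect another structure of the samples was not tested. The others that part all pairs gave 0 to 2. The difference between the plasmids is the biological explanation that the design names. The limma fit compared the plasmid groups, but whether the plasmid or something else that differs between the groups is the cause was not tested. This explanation therefore stays open.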
